A study of Cynoglossus semilaevis with 24 samples.

How the data were processed

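The sources used here were the sample labels, the title of the series, the deposited gene table and a gene table of the reference assembly Cse_v1.0. Per the file headers, the authors gave FPKM and an estimated count for each gene in each of 24 libraries. The table has 22773 entries: 20373 carry an NCBI gene identifier and 2400 are unannotated loci. Of the identifiers, 19502 were found in the reference, which gave 3668 gene symbols and placed 882 genes on Z, 246 on W and 18374 on autosomes; 871 were not found. In 219 genes every value was 0. Per the submitters' processing notes, TopHat2 2.0.3.12 and Bowtie2 were used; their role, the quantification tool, the genome build, the annotation and any filter were not given in the sources used here. Raw reads were not analysed here.

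The deposited counts were whole numbers in 97.1 to 98.4% of values, depending on the library, and were rounded. Estimated counts summed to between 10032337 and 25293744 per library. Sex and tissue came from the labels, and the W-linked genes bore out the sex of each library. A pool held 5 fish, so spread between single fish was not seen. The replicate numbers of female and male pools of a tissue did not pair, and the replicate number was not in the fit. Same-numbered female pools did pair across brain, pituitary and liver (correlation of deviations 0.11 to 0.336 in all 9 pairs). Male pools of the same number were positively correlated there too, less closely (0.0261 to 0.243). The test among tissues and the overlaps treat libraries as independent.

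In each tissue females were compared with males by the quasi-likelihood test of edgeR, with TMM scaling and a robust fit, for genes at 1 FPKM or more in at least 3 of 6 libraries. Every edgeR adjusted p is a Benjamini-Hochberg adjustment over the genes tested in that tissue. log2 differences are female minus male. The SE of a log2 difference is its absolute value over the square root of the quasi-likelihood F statistic. Levels are means of FPKM with the SD over 3 pools, while folds come from the fit on counts, so a fold and the ratio of 2 FPKM means can differ, above all in gonad. Where one sex had no count, the fold is a lower bound that sets 3 counts over that group. The design written before the files were opened foresaw limma on FPKM unless counts were present. Counts were present, so edgeR was used, also for the test of the sex difference among tissues and for the lists.

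Whether the sex difference of a gene differed among brain, pituitary and liver was tested in 1 edgeR fit of 18 libraries with a term for sex by tissue. Opposite directions were counted only where that term was called and the gene was called in each of the tissues. Lists of genes were fixed before the files were opened: GH-IGF axis, pituitary hormones, appetite and hypothalamic peptides, reproductive neuroendocrine, steroidogenesis and sex steroid receptors, lipid and cholesterol synthesis, fatty acid oxidation and gluconeogenesis, immediate early and stress, endoplasmic reticulum protein folding, oxidative phosphorylation, cell cycle, estrogen-responsive liver secretion, testis differentiation, ovary and oocyte, meiosis, spermatogenesis and sperm flagellum, and 6 lists of other cell types. Lists with at least 5 tested members were tested with camera of limma at the preset correlation of 0.01, adjusted by Benjamini-Hochberg over all lists and tissues. The camera test was repeated with a correlation estimated from the data. KEGG pathways (6194 genes) and GO processes (9833 genes) were tested with one-sided Fisher's exact tests on the called genes of each sex, adjusted by Benjamini-Hochberg. Overlaps between tissues used the same test on the genes tested in both.

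Genes were named by rule: the 6 largest called differences in each direction per tissue with a known product and groups that did not overlap, key genes chosen beforehand, the leading called genes of lists that passed or had 5 or more calls, the W-linked genes with the highest level, and 10 genes with the same direction in all 4 tissues. The largest differences outside W were added after the values were seen. For the Z chromosome, the median of log2(FPKM + 1) over tested Z-linked genes minus that over autosomal genes was taken in each library, and the sexes were compared by an exact permutation of the 6 libraries of a tissue. The levels of lists from other tissues were read from list members above 300 FPKM in the source tissue.

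Alternatives fixed before the files were opened were pseudocount 0.1, no filter, a filter at 5 FPKM, median-ratio scaling, quantile normalization, all 24 libraries in one fit, ordinary eBayes, a least difference of 2-fold, a term for replicate number, leaving out each library in turn, and an estimated correlation for the lists. Those that take a log scale were run with limma on log2 FPKM. Chosen after the data were seen were limma on log2(FPKM + 1), DESeq2, no scaling beyond the count total, leaving out both pituitary libraries with gonad transcripts, voom without a block for the test among tissues, a replicate term for the lists, and the overlap under each alternative. On the log2(FPKM + 1) scale differences of weakly expressed genes shrink, so their folds there are smaller.

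The methods were tried on simulated counts with 200 changed genes, as many raised as lowered. Far more genes were called in the real data, above all in gonad (13632 of 16195), so the shares below need not hold there. In brain, pituitary, liver and gonad 80, 69, 54 and 55% of 2-fold changes and 99, 97, 94 and 92% of 4-fold changes were recovered, with 6.28, 8.29, 4.52 and 6.37% false genes among those called. For the test among tissues the shares were 35 and 76%, with 4.31% false. A planted pathway term ranked 1 of 141, and 11 other terms were called. Whether these share genes with the planted term or were false calls was not checked. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.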

Results

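Gene expression was measured by RNA sequencing in brain, pituitary, liver and gonad of Chinese tongue sole aged 2 years, a flatfish whose females outgrow its males. Tissue and genetic sex made 8 groups of 3 libraries. Each library was a pool of 5 fish, so every p-value below rests on 3 pools per sex and not on single fish. The 8 groups gave 24 libraries, and the labels do not say whether the pools of different tissues came from the same fish. Estimated counts summed to between 10032337 and 15409531 per library, apart from female gonad 1 with 25293744. Genes on the W chromosome, which females alone carry, followed the labels in all 24 libraries: 95 to 179 of them reached 1 FPKM in each female library and 12 to 34 in each male library. A gene was called different at an adjusted p under 0.05. In every called gene given below with its level or fold, except where stated, the 3 female pools lay wholly above or wholly below the 3 male pools.

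The comparison of pituitaries asked which hormone and regulator genes differ between the sexes in the gland that releases growth hormone. Female pituitaries held 3.93-fold more growth hormone transcript (gh1) than male ones, at 84266 ± 17727 against 20955 ± 5697 FPKM (SD, n = 3 pools each; log2 difference 1.98, SE 0.24, edgeR adjusted p = 0.000902). The gene for the transcription factor that drives growth hormone expression, pou1f1, was 3.45-fold higher in females (220.3 ± 41.6 against 63.1 ± 14.6 FPKM, edgeR adjusted p = 0.000121). The leptin receptor gene lepr was 3.28-fold higher in females, at 59.7 ± 10.4 against 17.8 ± 4.15 FPKM. The agouti-related protein gene agrp was 15.3-fold higher, at 74.0 ± 13.9 against 4.76 ± 2.83 FPKM. Males had 2.09-fold more of the pro-opiomelanocortin-like gene LOC103393769 (41264 ± 11630 against 20037 ± 1484 FPKM) and 2.09-fold more of the somatolactin gene smtla (13999 ± 3575 against 6796 ± 462 FPKM).

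**Figure D1:**
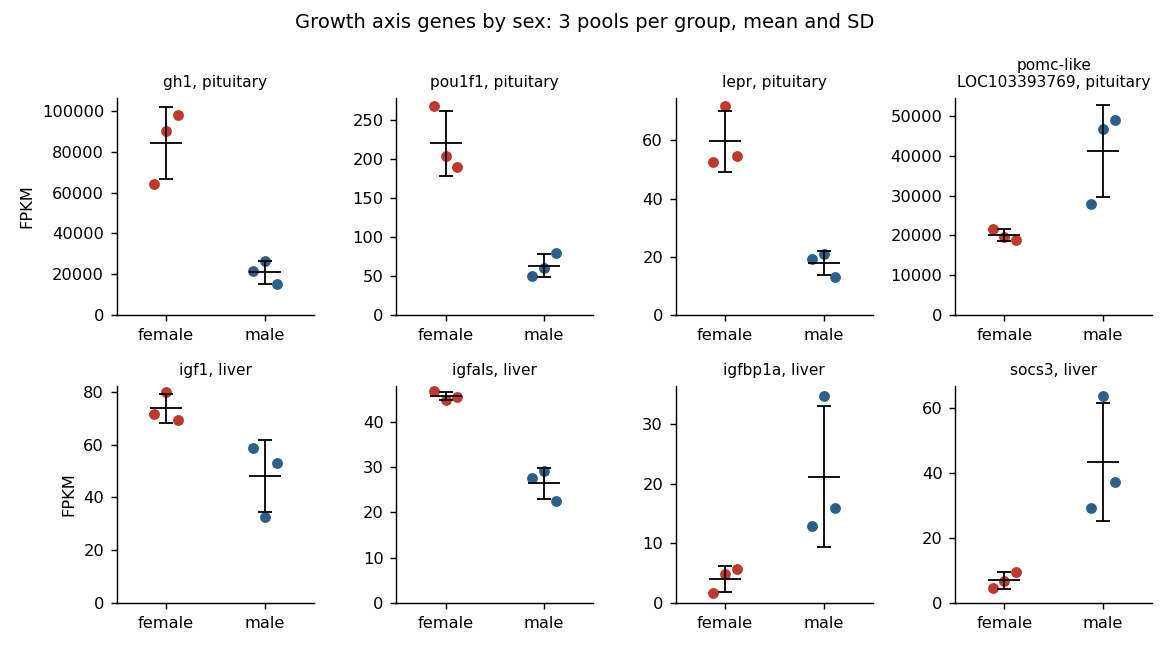
FPKM of 8 growth axis genes in each pool of pituitary (upper row) and liver (lower row); points are pools, the long bar is the mean of 3 pools and the whiskers are 1 SD. In pituitary the 3 female pools lie above the 3 male pools for gh1, pou1f1 and lepr and below them for LOC103393769; in liver igf1 was not called.

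Among the pituitary hormones and their processing genes, 11 of 15 were called, 4 higher in females and 7 in males (11 adjusted over the list alone). The prohormone convertase gene pcsk2 was 2.16-fold higher in males and the granule protein gene chga 1.78-fold higher in females. The list as a whole did not move one way (camera adjusted p = 0.660). Prolactin (prl, 6448.5 ± 719.6 against 5209 ± 1436 FPKM, log2 difference 0.29, SE 0.19) and the pro-opiomelanocortin-like gene LOC103389827 (edgeR adjusted p = 0.901) were not called. Neither were the luteinizing hormone gene lhb (edgeR adjusted p = 0.133) and the thyrotropin gene tshba (edgeR adjusted p = 0.140), although lhb in pituitary was called without female pituitary 1 (0.00506, range 0.00506 to 0.492 over the alternatives) and tshba in pituitary without female pituitary 2 (0.0086), in the fit of all 24 libraries, with ordinary eBayes and with a term for replicate number (range 0.005 to 0.302). Quantile normalization ended the calls of smtla in pituitary (limma adjusted p = 0.136, range 4.92e-10 to 0.136 over the alternatives) and of LOC103393769 in pituitary (0.0570, range 5.75e-08 to 0.0570). In the GH-IGF axis list, 13 of 38 genes were called, 5 higher in females and 8 in males (17 adjusted over the list alone; camera adjusted p = 0.691); the binding protein gene igfbp1a was 3.53-fold higher in males and the somatostatin receptor gene LOC103393002 1.81-fold higher in females. Of the reproductive neuroendocrine list, 2 of 17 genes were higher in females and 7 in males (10 adjusted over the list alone; camera adjusted p = 0.126), with the estrogen receptor gene esr1 1.86-fold and the dopamine receptor gene drd2 1.71-fold higher in males and the progesterone receptor gene pgr 2.43-fold higher in females. Aromatase (LOC103380488), which makes estrogen from androgen, was 3.44-fold higher in males (41.4 ± 5.41 against 12.3 ± 3.91 FPKM).

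Immediate early and stress genes in pituitary were called in 8 of 19 cases, 7 of them higher in males (9 adjusted over the list alone). The list passed its test (camera adjusted p = 0.0491, and adjusted p = 0.642 with an estimated correlation). The osmotic stress transcription factor gene tsc22d3 was 6.84-fold, the stress factor gene atf3 2.95-fold and the chaperone gene hsp90aa1 2.37-fold higher in males. The 1 member higher in females was egr1, named here after its values were seen. Lipid and cholesterol synthesis genes were called in 12 of 30 cases, 5 higher in females and 7 in males (12 adjusted over the list alone; camera adjusted p = 0.311), among them acly (2.06-fold), scdb (2.17-fold) and ldlr (2.18-fold), all higher in males. The largest male excesses were in nmrk2, a kinase of the NAD pathway (28.2-fold, 33.4 ± 7.47 against 1.21 ± 0.514 FPKM), gdf15 (22.4-fold), the protease gene adamts9 (17.5-fold) and the thrombospondin-like gene LOC103393533 (12.8-fold). Genes higher in males held 27 of 76 tested genes of ECM-receptor interaction where 11.02 would fall by chance, and 20 of 56 of glycolysis and gluconeogenesis against 8.12 (one-sided Fisher's exact test, adjusted p = 0.000594 and 0.00534).

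In total 4086 of 15313 pituitary genes were called, 1902 higher in females and 2184 in males, and 1167 of them differed at least 2-fold. At an unadjusted p under 0.05 there were 6018, and 44.2% of genes had groups that did not overlap, against 10% by chance. Female pituitary 3 and male pituitary 3 carried transcripts of the oocyte list at 5.89 and 6.48 times the other pools of their sex (medians of 20 genes), and female pituitary 3 also carried the hepatocyte list at 3.27 times and the pancreas list at 2.31 times the other female pituitaries. Without both of these libraries numbered 3 the count of called genes was 3409, and 71.5% of the main calls were kept. Without female pituitary 2 the count was 2661.

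Liver, where growth hormone acts, was compared to learn which growth and metabolic genes differ between the sexes. Male livers had far more transcript of immediate early and stress genes: 10 of 15 were called, all higher in males (14 adjusted over the list alone). The nuclear receptor gene nr4a3 was 43.7-fold higher in males (5.98 ± 1.28 against 0.173 ± 0.127 FPKM, edgeR adjusted p = 1.75e-05). The immediate early genes fosab, fosb and jun were 16.3-fold, 12.1-fold and 8.84-fold higher, with fosab at 381 ± 165 FPKM in males and 25.2 ± 14.0 in females (n = 3 pools each). The list had the smallest p of any list in liver (camera adjusted p = 3.24e-20, and adjusted p = 0.144 with an estimated correlation), with a median log2 difference of -1.48. Outside the list, the nr4a1-like gene LOC103386020 was 19.0-fold higher in males.

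**Figure D2:**
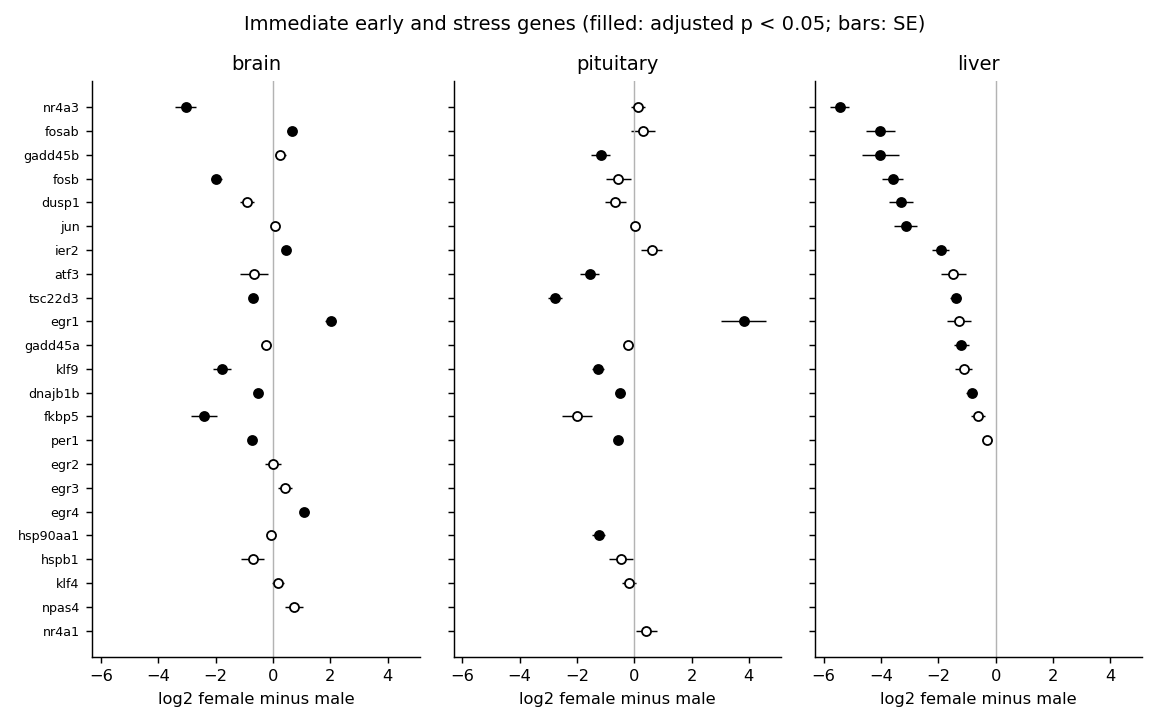
log2 female minus male of each tested immediate early and stress gene in brain, pituitary and liver; points are estimates, bars are 1 SE, and filled points were called. In liver the 10 called genes all lie left of 0; in brain 4 called genes lie right of 0 and 7 left of it.

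The gene for insulin-like growth factor 1, igf1, stood at 73.7 ± 5.47 FPKM in female and 48.1 ± 13.7 FPKM in male livers and was not called (log2 difference 0.49, SE 0.24, edgeR adjusted p = 0.267, range 0.109 to 0.459 over the alternatives). The growth hormone receptor gene ghr (24.5 ± 2.29 against 29.4 ± 2.23 FPKM, edgeR adjusted p = 0.257) and the receptor-like gene LOC103389092 (edgeR adjusted p = 0.780) were not called either. In the GH-IGF axis list, 6 of 20 genes were called, 3 in each direction (9 adjusted over the list alone; camera adjusted p = 0.590). The cytokine signalling inhibitor gene socs3 was 6.68-fold higher in males (43.4 ± 18.2 against 6.95 ± 2.57 FPKM). The acid-labile subunit, whose product carries IGF in blood, is coded by igfals; igfals in liver was 1.61-fold higher in females (45.6 ± 0.958 against 26.4 ± 3.42 FPKM, edgeR adjusted p = 0.0379), and lost its call in the fit of all 24 libraries and without female liver 1, 2 or 3 or male liver 2 or 3 (adjusted p = 0.0843, 0.0868, 0.102, 0.0521 and 0.148 without each in turn, range 0.00832 to 0.268 over the alternatives). The binding protein gene igfbp1a in liver was 5.59-fold higher in males (21.2 ± 11.9 against 4.07 ± 2.17 FPKM, edgeR adjusted p = 0.0284), and lost its call without female liver 2 or 3 or male liver 3 (adjusted p = 0.0885, 0.0585 and 0.054), with pseudocount 0.1, without a filter and without scaling (range 6.91e-08 to 0.128).

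Lipid and cholesterol synthesis genes shifted toward females in liver (median log2 difference 0.97, camera adjusted p = 0.00118, and adjusted p = 0.776 with an estimated correlation). Of 29 members 6 were called, 3 higher in each sex (15 adjusted over the list alone). The acyltransferase gene gpam in liver was 1.98-fold higher in females and lost its call without female liver 3 or male liver 3 (adjusted p = 0.0585 and 0.0598, range 0.00108 to 0.0598 over the alternatives). The 4 vitellogenin genes, which code for yolk proteins made in liver, stayed under the filter, the highest at a mean of 0.487 FPKM over the 6 libraries, and the estrogen receptor gene esr1 was not called (1.25 ± 0.282 against 1.21 ± 0.00577 FPKM, edgeR adjusted p = 0.917). Of the other estrogen receptor genes, esr2, named after its values were seen, was higher in females (15.3 ± 0.527 against 4.49 ± 0.494 FPKM, edgeR adjusted p = 0.000431) and esr2a was not called (edgeR adjusted p = 0.368). The estrogen-responsive secretion list did not pass (camera adjusted p = 0.660). The vitellogenin genes were not in this test, and the list also holds egg envelope genes. Transcripts of the oocyte list stood in female liver 1 at 0.176% of their ovary level and in female liver 2 at 0.0561%. The test therefore does not decide whether estrogen-responsive secretion differed in liver. The W-linked heparin cofactor 2-like gene LOC103397136 reached 207 ± 18.5 FPKM in female and 0.117 ± 0.0153 FPKM in male livers. Genes higher in males held 23 of 143 tested genes of insulin signaling against 7.83 by chance and 20 of 124 of FoxO signaling against 6.79 (one-sided Fisher's exact test, adjusted p = 0.000371 and 0.00123).

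In total 721 of 10566 liver genes were called, 199 higher in females and 522 in males, with 449 at least 2-fold apart. At an unadjusted p under 0.05 there were 2388, and 26.5% of genes had groups that did not overlap, against 10% by chance. The oocyte list stood in female liver 1 at 3.14 times the other female pools. The count was 344 without female liver 3, 352 without male liver 3, 355 without female liver 2, 318 with a filter at 5 FPKM and 1715 with all 24 libraries in one fit; without TMM scaling, which moved the median of all liver genes from 0.02 to 0.12 on the log2 scale, 39.0% of calls were higher in females where TMM gave 27.6%.

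Brain was compared for the neuropeptides and receptors that govern growth, feeding and reproduction. The galanin gene gal was 6.45-fold higher in males (62.6 ± 16.2 against 9.97 ± 1.78 FPKM, n = 3 pools each, log2 difference -2.69, SE 0.22, edgeR adjusted p = 3.68e-05). The cholecystokinin gene cck, whose peptide signals satiety, was 3.05-fold higher in females (65.5 ± 11.96 against 20.7 ± 5.997 FPKM, edgeR adjusted p = 0.00256). The androgen receptor gene ar was 2.04-fold higher in females, at 5.62 ± 0.302 against 2.67 ± 0.332 FPKM. Blood and immune genes leaned to females: 8 of 18 were called, all of them higher in females (9 adjusted over the list alone; camera adjusted p = 0.00120, and adjusted p = 0.642 with an estimated correlation). The macrophage receptor gene csf1r was 1.94-fold, the peroxidase gene mpx 5.38-fold and the B-cell receptor gene cd79b 3.98-fold higher in females. Neuron and glia genes leaned the other way in the same brains, with 1 of 24 called higher in females and 5 in males (9 adjusted over the list alone; camera adjusted p = 0.0773).

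In the appetite and hypothalamic peptide list, 6 of 24 genes were called in brain, 2 higher in females and 4 in males (7 adjusted over the list alone; camera adjusted p = 0.389). The GH-IGF axis list had 7 of 37 called, 1 higher in females and 6 in males (6 adjusted over the list alone; camera adjusted p = 0.499). Its somatostatin gene sst1.2 in brain, which codes for an inhibitor of growth hormone release, was 1.62-fold higher in males (25.9 ± 3.87 against 16.5 ± 3.50 FPKM, edgeR adjusted p = 0.0133) and lost its call without female brain 1 or 2 (adjusted p = 0.0621 and 0.0605) and in the fit of all 24 libraries (range 0.00579 to 0.514 over the alternatives). The somatostatin gene sst1.1 in brain was not called (16.3 ± 1.66 against 6.84 ± 5.77 FPKM, edgeR adjusted p = 0.127) but was called without male brain 1 (adjusted p = 0.000287, log2 difference 2.15 in place of 1.18), with DESeq2 and with a term for replicate number (range 0.000287 to 0.496). Neuropeptide Y (npy in brain, 8.24 ± 1.40 against 11.5 ± 4.94 FPKM, edgeR adjusted p = 0.266) was called only without male brain 2 (0.0159, range 0.0159 to 0.613), and the gonadotropin-releasing hormone gene gnrh2 was not called (edgeR adjusted p = 0.680). The growth hormone-releasing hormone gene ghrh averaged 0.653 FPKM and was not tested. Aromatase (LOC103380488 in brain) was 1.45-fold higher in males (13.8 ± 2.04 against 9.80 ± 1.16 FPKM, edgeR adjusted p = 0.00910), and lost its call without male brain 1 (adjusted p = 0.0512) and in the fit of all 24 libraries (range 0.00445 to 0.0974).

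Lipid and cholesterol synthesis genes were called in 9 of 31 cases in brain, 1 higher in females and 8 in males (9 adjusted over the list alone; camera adjusted p = 0.267), with acly 1.41-fold and the regulator gene srebf1 1.32-fold higher in males. The Z-linked copy of the unfolded protein regulator, xbp1, was 2.77-fold higher in males (181 ± 22.1 against 67.3 ± 4.01 FPKM). The W-linked copy LOC103396890 was higher in females in the same brains (log2 difference 0.507, edgeR adjusted p = 0.00242). Of the 33 endoplasmic reticulum folding genes, 3 were higher in females and 5 in males (9 adjusted over the list alone; camera adjusted p = 0.506). Immediate early and stress genes went both ways: 4 of 22 were higher in females and 7 in males (12 adjusted over the list alone; camera adjusted p = 0.216), with nr4a3 8.28-fold and fosb 3.93-fold higher in males and egr4 2.14-fold higher in females. The largest male excess was in nmrk2, at 16.8-fold, and adamts9 was 8.21-fold higher in males. Genes higher in females held 33 of 154 tested genes of cytokine-cytokine receptor interaction against 15.4 by chance (one-sided Fisher's exact test, adjusted p = 0.00183).

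In total 3318 of 16385 brain genes were called, 1533 higher in females and 1785 in males, and among the 542 at least 2-fold apart 361 were higher in females, 157 of them W-linked, and 181 in males. At an unadjusted p under 0.05 there were 5443, and 37.6% of genes had groups that did not overlap, against 10% by chance. Male brain 1 carried the oocyte list at 9.72 times the other male brains. The count was 1122 with all 24 libraries in one fit, and without TMM scaling 57.0% of calls were higher in females where TMM gave 46.2%.

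Gonads compared ovary with testis, 2 different organs. The testis-determining gene dmrt1, on the Z chromosome, stood at 49.4 ± 11.8 FPKM in testis and was 527-fold lower in ovary (n = 3 pools each, edgeR adjusted p = 3.90e-09). Anti-Mullerian hormone (amh) was 5.70-fold and sox9 14.9-fold higher in testis. The oocyte growth factor gene gdf9 stood at 158 ± 11.8 FPKM in ovary and 0.313 ± 0.0751 in testis (868-fold, edgeR adjusted p = 8.16e-11). The ovarian regulator gene foxl2 was 15.1-fold higher in ovary (7.11 ± 2.03 against 0.827 ± 0.431 FPKM). The aromatase-like gene LOC103378914 in gonad, at 4.37 ± 2.88 FPKM in ovary and 7.07 ± 0.909 in testis, was not called (log2 difference 0.14 after scaling, edgeR adjusted p = 0.776, range 0.0407 to 0.933 over the alternatives), and was called only without female gonad 2 (adjusted p = 0.0407). Its sign was not stable: the log2 difference was -0.91 with pseudocount 0.1 and 0.68 without female gonad 2.

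Of 14 testis differentiation genes 12 were called, all higher in testis (12 adjusted over the list alone; camera adjusted p = 0.00657, and adjusted p = 0.642 with an estimated correlation). Meiosis genes were called in 24 of 25 cases, 19 higher in testis and 5 in ovary (24 adjusted over the list alone; camera adjusted p = 4.82e-05, and adjusted p = 0.642 with an estimated correlation): sycp3 was 483-fold and hormad1 520-fold higher in testis, and the recombination gene rad51c 27.2-fold higher in ovary. Spermatogenesis and sperm flagellum genes were called in 73 of 79 cases, 57 higher in testis and 16 in ovary (73 adjusted over the list alone; camera adjusted p = 3.20e-05, and adjusted p = 0.738 with an estimated correlation), with tex14 244-fold higher in testis. The ovary and oocyte list had 40 of 43 called, 37 higher in ovary and 3 in testis (41 adjusted over the list alone; camera adjusted p = 2.50e-25, and adjusted p = 0.144 with an estimated correlation), among them the germ plasm organizer buc at 464-fold. The estrogen-responsive secretion list had 28 of 29 called, 25 higher in ovary and 3 in testis (28 adjusted over the list alone; camera adjusted p = 1.50e-18, and adjusted p = 0.144 with an estimated correlation). Its leading members were egg envelope genes, such as zp3f.1 at 1498 ± 56.6 FPKM in ovary and 1.13 ± 0.193 in testis.

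Ovary also had more transcript of 29 of 33 oxidative phosphorylation genes, with 1 higher in testis (31 adjusted over the list alone; camera adjusted p = 0.000170, and adjusted p = 0.738 with an estimated correlation), such as sdha at 10.5-fold. Of 33 endoplasmic reticulum folding genes 28 were higher in ovary and 3 in testis (31 adjusted over the list alone; camera adjusted p = 0.00734, and adjusted p = 0.611 with an estimated correlation), with sec61b 7.73-fold higher in ovary and xbp1 6.20-fold higher in testis. Immediate early and stress genes were higher in testis in 18 of 20 cases and higher in ovary in 1 (19 adjusted over the list alone; camera adjusted p = 0.0491, and adjusted p = 0.642 with an estimated correlation); nr4a3 was 34.8-fold higher in testis and nr4a1 8.78-fold higher in ovary. Skeletal muscle genes were higher in testis in 19 of 33 cases and in ovary in 6 (24 adjusted over the list alone; camera adjusted p = 0.0491, and adjusted p = 0.642 with an estimated correlation), with nebulin (neb) 44.0-fold higher in testis. Steroidogenesis genes were called in 21 of 27 cases, 15 higher in testis and 6 in ovary (21 adjusted over the list alone; camera adjusted p = 0.419), with hsd3b1 19.0-fold and the androgen synthesis gene cyp11c1 2.85-fold higher in testis. In the GH-IGF axis list 28 of 31 were called, 13 higher in ovary and 15 in testis (29 adjusted over the list alone); its median log2 difference was -0.51 while its mean was 0.26 and its test pointed to ovary (camera adjusted p = 0.816). Within it the gonadal growth factor gene igf3 was 28.4-fold higher in testis and the somatostatin gene sst6.1 85.4-fold higher in ovary. The melanin-concentrating hormone gene pmch, at 20.9 ± 0.685 FPKM in ovary, had no count in testis, so that it was at least 182-fold higher in ovary. The transcription factor gene pax1 was at least 1219-fold higher in testis, with no count in ovary.

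In total 13632 of 16195 gonad genes were called, 6280 higher in ovary and 7352 in testis, with 11275 at least 2-fold apart. At an unadjusted p under 0.05 there were 13748, and 86.3% of genes had groups that did not overlap, against 10% by chance. Female gonad 2 carried the hepatocyte list at 25.7 times and the pancreas list at 31.9 times the other ovary pools, while the trypsin-like gene LOC103382459 was high in all 3 ovary pools (742 ± 97.0 FPKM, log2 difference from testis 12.03). With TMM scaling the median log2 difference of all gonad genes was -0.24, with median-ratio scaling -0.08 and without scaling -1.04; without scaling 31.7% of calls were higher in ovary where TMM gave 46.1%.

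Z-linked genes were lower in females in each tissue. Against autosomal genes their per-library median fell by 0.45 on the log2 scale in female relative to male brain, by 0.38 in pituitary, by 0.31 in liver and by 0.83 in gonad. In brain the female value was -0.39 ± 0.05 and the male value 0.06 ± 0.02 (SD, n = 3 pools). The exact two-sided permutation p was 0.1 in each tissue, the smallest that 20 assignments of 3 against 3 pools can give. In brain 417 of 696 tested Z-linked genes were called higher in males and 12 in females, and Z-linked genes made up 23.4% of all brain genes called higher in males. The Z-linked counts called higher in males and in females were 245 and 28 of 656 in pituitary, 105 and 3 of 468 in liver, and 397 and 172 of 678 in gonad. In gonad the share of Z-linked genes called (83.9%) was close to that of autosomal genes (84.2%).

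**Figure D3:**
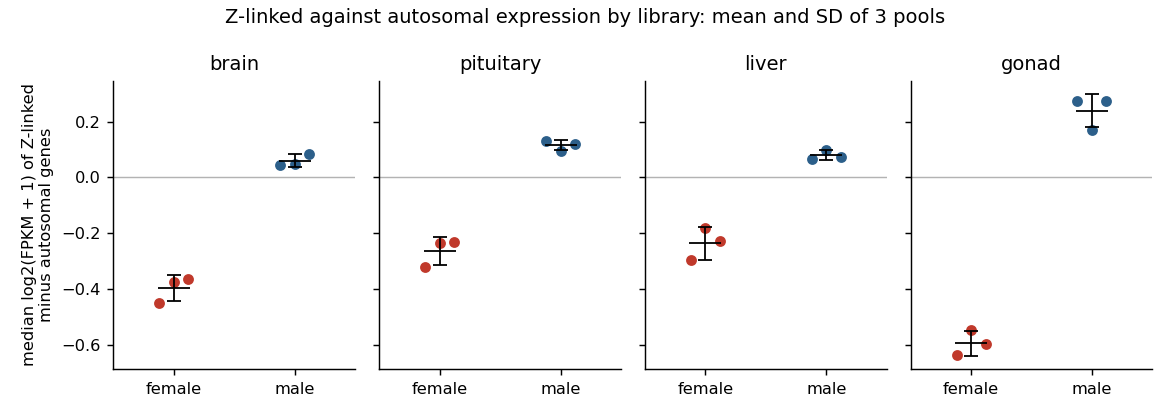
Median log2(FPKM + 1) of tested Z-linked genes minus that of tested autosomal genes in each library; points are pools, the long bar is the mean of 3 pools and the whiskers are 1 SD. The 3 female pools lie below the 3 male pools in each tissue, with brain means of -0.39 and 0.06.

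W-linked genes were called higher in females in 161 of 170 cases in brain, 133 of 147 in pituitary, 76 of 86 in liver and 85 of 100 in gonad. The W-linked ribosomal protein L6-like gene LOC103397139 stood at 322 ± 23.9 FPKM in female brains and 2.08 ± 2.31 in male brains. Male brain 1, at 4.72, carried most of the male level. LOC103397139 in brain had a log2 difference of 7.17, and of 8.71 without male brain 1. The W-linked kinase gene LOC103397124 (A-Raf-like) had no count in male brains and was at least 383-fold higher in females. Some genes assigned to W were expressed in males as well: the xbp1 copy LOC103396890 stood at 108 ± 5.83 FPKM in female and 47.0 ± 5.73 in male pituitaries. Copies of a gene on Z and W can share reads, so values of such pairs are uncertain.

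The tissues were then compared with one another. Of the genes tested in brain, pituitary and liver, 89 were higher in females in all 3 tissues, 68 of them W-linked, and 160 were higher in males. Brain and pituitary shared 750 genes higher in males where 228 would be shared by chance (one-sided Fisher's exact test, adjusted p = 1.70e-253). They shared 519 higher in females where 173 would be (same test, adjusted p = 6.76e-142), 393 of them not W-linked. Z-linked genes made up 23.4% of genes called higher in males in brain and 11.2% in pituitary. They were not taken out of the male counts given here, so sex-linked and other genes are not set apart there. Brain and gonad shared 459 genes higher in females, against 493 by chance (same test, adjusted p = 0.981), but 809 higher in males against 635.5 (adjusted p = 1.73e-22). Pituitary and gonad shared 712 higher in females against 629.6, 641 of them not W-linked, and 1066 higher in males against 840.3. Liver and gonad shared 100 higher in females against 70, 44 of them not W-linked, and 271 higher in males against 195.4. Genes called in the same direction in all 4 tissues numbered 60 in females, 54 of them W-linked, and 104 in males. The count of 249 genes shared by brain, pituitary and liver was 154 without female liver 3, 155 without male liver 3 and 165 without female liver 2.

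Other lists did not pass in any tissue in the main test. Their smallest camera adjusted p was 0.0616 for cell cycle in gonad (17 of 27 genes higher in ovary, 5 in testis, 22 adjusted over the list alone), 0.0720 for pituitary hormones in brain, 0.0773 for neurons and glia in brain, 0.126 for reproductive neuroendocrine genes in pituitary, 0.143 for steroidogenesis and for hepatocyte genes in liver, 0.157 for exocrine pancreas in gonad and 0.175 for fatty acid oxidation and gluconeogenesis in gonad. The appetite and hypothalamic peptide list had 0.325 in liver and the GH-IGF axis list 0.499 in brain. The photoreceptor and pineal list had under 5 tested members in each tissue and was not tested. None of the list calls held with an estimated correlation in place of the preset one: the smallest adjusted p was then 0.144.

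**Figure D4:**
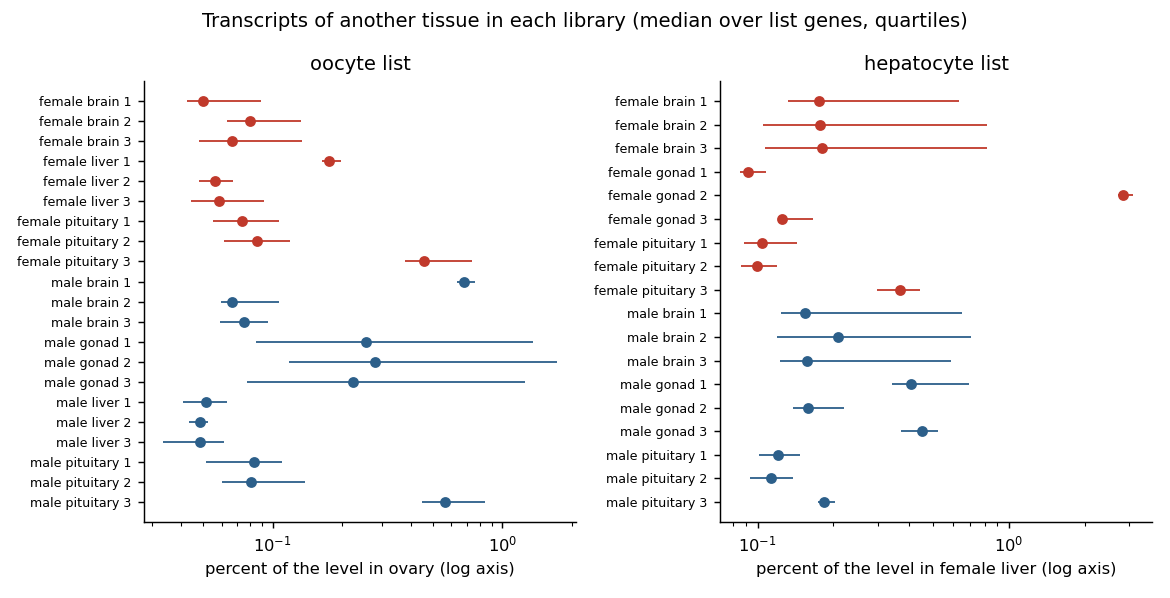
Median level of the oocyte list as a percent of its level in ovary (left) and of the hepatocyte list as a percent of its level in female liver (right), in each library of the other tissues, on log axes; whiskers are the quartiles over the genes of the list. Male brain 1, both pituitary libraries numbered 3 and female liver 1 stand apart from their groups on the left, and female gonad 2 and, less far, female pituitary 3 (0.370%) on the right.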

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

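The tests on blood cells, on a response shared by tissues and on handling were chosen after the result was seen. The size of the sex difference varied among brain, pituitary and liver in 1569 of 17770 genes (edgeR quasi-likelihood test of the sex by tissue term with Benjamini-Hochberg adjustment; 4367 at an unadjusted p under 0.05). Of 60 splits of the libraries within each tissue, 1 gave a count as large, the real one, and the highest other count was 562. The splits shuffled the sex labels within each tissue. They stand for no sex difference at all and not for an equal one in the 3 tissues, so they do not decide whether it varied among tissues. These splits and the fit treat libraries as independent, although same-numbered pools of a sex were correlated across these tissues, male pools less closely than female ones. The genes whose sex difference differed among brain, pituitary and liver numbered 2440 with a replicate block for the pool (voom), against 2173 with voom and no block. In 134 genes the direction was opposite in 2 of the 3 tissues, 103 of them between brain and pituitary, 19 between brain and liver and 25 between pituitary and liver. All genes below stood out because of this difference between tissues, and each p is the edgeR adjusted p of that term. A gene under the filter in a tissue could still enter that fit, so its p can rest in part on a low level there. Among the genes below, agrp, chga, pcsk2, scg2, aromatase and hsp90aa1 were under the filter in liver.

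In the growth axis, gh1 was higher in females in pituitary (log2 difference 1.98; adjusted p = 0.00076). In brain and liver gh1 stood at 0.0804 and 0.0582% of its pituitary level, in liver much as the other hormone genes did (0.0514 to 0.0767%), so its values there (-0.13 and -0.08) are not read as an absence of a sex difference in gh1 expression. The leptin receptor gene lepr followed gh1, at 1.71 in pituitary (adjusted p = 0.00015), and so did agrp (3.94 in pituitary, 0.67 in brain; adjusted p = 0.0032), the somatostatin receptor gene sstr2a (1.66 in pituitary; adjusted p = 0.005) and the growth hormone receptor gene ghr (0.72 in pituitary, -0.37 in liver, where it was not called; adjusted p = 0.0073). The binding protein gene igfbp1a was higher in males in pituitary (-1.82) and liver (-2.48) but not in brain (0.16; adjusted p = 0.017), and igfbp2 was higher in females in brain (0.47) and in males in pituitary (-0.50; adjusted p = 0.03). Among secretory genes, scg2 was higher in males in brain (-0.32) and in females in pituitary (0.52; adjusted p = 0.015). The brain calls of scg2 and igfbp2 were lost in the fit of all 24 libraries (adjusted p = 0.156 and 0.296, ranges 0.000312 to 0.156 and 8.54e-05 to 0.296 over the alternatives). The genes chga (adjusted p = 0.013), p4hb (adjusted p = 0.02) and pcsk2 (adjusted p = 0.025) differed more in pituitary than in brain.

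Among receptor and steroid genes that stood out, the estrogen receptor gene esr1 was called in pituitary alone of the 3 tissues, higher in males (-0.90; adjusted p = 0.018). The dopamine receptor gene drd2 was called in pituitary (-0.78) and not in brain (-0.18; adjusted p = 0.027); it was under the filter in liver, where the fit among tissues put its difference 4.25 below that of brain, so its p does not rest on pituitary alone. The androgen receptor gene ar was higher in females in brain alone (1.03; adjusted p = 0.023). Aromatase (LOC103380488) was higher in males by more in pituitary (-1.78) than in brain (-0.54, adjusted p = 0.022). The gene hsd17b12 was higher in males in brain (-0.96, adjusted p = 0.034) and under the filter in liver. In liver the fit among tissues put its difference 4.39 above that of brain, and in pituitary 0.624 above, so its p does not rest on brain and pituitary alone. For lipid genes, ldlr was higher in males in pituitary alone (-1.12, adjusted p = 0.003) and was not called in brain (0.21) or liver (0.22). The gene scdb had its largest male excess in pituitary (adjusted p = 0.044) and insig1 in liver (-1.04, adjusted p = 0.038). The gene gpam was higher in females in liver alone (0.98, adjusted p = 0.013). The call of insig1 in liver was lost without female liver 1, 2 or 3 or male liver 3 (adjusted p = 0.0563, 0.0635, 0.0825 and 0.0937), with pseudocount 0.1, quantile normalization and limma on log2(FPKM + 1) and without scaling (range 2.86e-05 to 0.1 over the alternatives). The macrophage gene csf1r had its largest female excess in pituitary (1.57; adjusted p = 0.022) and mpx in brain (2.43; adjusted p = 0.006).

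Other genes with a sex difference that varied were adamts9 (-3.04 in brain, -4.13 in pituitary; adjusted p = 0.0043), the thrombospondin-like gene LOC103393533 (adjusted p = 0.034), gdf15 (-4.49 in pituitary; adjusted p = 0.0084), arl14 (-3.73 in pituitary; adjusted p = 0.016), the dynein gene dnah5 (1.86 in pituitary; adjusted p = 0.021) and piwil2, higher in females in brain (1.01) and in males in pituitary (-1.91; adjusted p = 0.0012). The call of piwil2 in brain, and with it the opposite direction, was lost without female brain 1 or 2 or male brain 2 (adjusted p = 0.0669, 0.0597 and 0.0654), with quantile normalization (log2 difference 0.26) and with limma on log2(FPKM + 1) (range 0.0161 to 0.293 over the alternatives). The actin-like gene LOC103398003 was higher in males in brain (-2.92) and in females in liver (1.76; adjusted p = 0.0024). The Z-linked gene LOC103397933 (formin-binding protein 1-like) was lower in females in brain (-0.33) and higher in pituitary (1.46) and liver (6.84; adjusted p = 2.3e-07). W-linked genes with a varied excess were LOC103397136 (adjusted p = 2.3e-07), the cathepsin-like gene LOC103397133 (adjusted p = 0.00058), LOC103396905 (adjusted p = 0.0058) and the xbp1 copy LOC103396890 (adjusted p = 0.0058). Of the genes in this paragraph, LOC103397136 passed the filter in liver alone, LOC103396905 in brain alone and dnah5 in pituitary alone. The genes adamts9 and piwil2 were under the filter in liver, and gdf15 in brain. For these genes a low level in a tissue and a different sex effect there were not told apart.

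Immediate early and stress genes, with related genes, made up the last group: nr4a3 (-3.05 in brain, 0.12 in pituitary, -5.45 in liver; adjusted p = 1.1e-05), jun (-3.14 in liver alone; adjusted p = 5.4e-05), tsc22d3 (largest in pituitary, -2.77; adjusted p = 0.00024), fosab (0.65 in brain, -4.03 in liver; adjusted p = 0.00064), LOC103386020 (adjusted p = 0.0011), gadd45b (adjusted p = 0.0023), hsp90aa1 (adjusted p = 0.0063) and fosb (adjusted p = 0.013).

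At the preset correlation, the male excess of immediate early and stress genes in liver did not rest on 1 male liver. The list kept a camera adjusted p of at most 8.55e-19 without each of them in turn. With an estimated correlation the list was not called even with all libraries (camera adjusted p = 0.144), so the point was not settled there. Blood cells in the male livers would have raised the blood and immune list there, whose median log2 difference was 0.112. A response that moves each gene the same way in every tissue was argued against by 2 genes, fosab and ier2, called in opposite directions in 2 tissues. Handling or a time to sampling that differed between the sexes could be the cause: the list had a negative median in brain, pituitary and liver. In brain the lean was weak, with a median of -0.158. There 4 called genes were higher in females and 7 in males, and the list did not pass (camera adjusted p = 0.216). The labels give no time or order of sampling, so this cause stayed open.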

How the results depend on the processing

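Of the called named genes, 37 of 71 in brain, 53 of 66 in pituitary, 31 of 41 in liver and 114 of 117 in gonad kept their call under every alternative, the 2-fold rule included, and 1 reversed. With a least difference of 2-fold, which is stricter by construction, 542 genes were left in brain, 1167 in pituitary and 449 in liver. All 24 libraries in one fit gave 1122 genes in brain and 1715 in liver, and a filter at 5 FPKM, which tests fewer genes, 318 in liver. Leaving out 1 library gave 2661 (without female 2) to 4376 (without male 3) in pituitary and 344 (without female 3) to 744 (without male 2) in liver. The genes whose sex difference differed among brain, pituitary and liver numbered 2589 with limma on log2(FPKM + 1), chosen after the data were seen, and 2440 with a replicate block for the pool, against 2173 with voom and no block. The Z-linked difference was -0.55 in brain with a filter at 5 FPKM, -0.39 with pseudocount 0.1 and -0.38 with that filter in liver, and -0.97 and -0.72 in gonad. Of 13 list calls 0 were left with an estimated correlation. With pseudocount 0.1 there were 16, 12 of them shared, and with a replicate block (chosen after the data were seen) 13, the hepatocyte list in liver gained (adjusted p = 0.0178) and the immediate early and stress list in gonad lost (adjusted p = 0.0575). The 249 genes shared by 3 tissues became 113 with a least difference of 2-fold, 164 with pseudocount 0.1, 96 with a filter at 5 FPKM, and 154 (without female liver 3) to 255 (without male brain 3) with 1 library left out. LOC103393769 in gonad turned from 0.66 to -0.14 with pseudocount 0.1, -0.078 with quantile normalization, -0.13 with limma on log2(FPKM + 1) and -0.15 without scaling. None of these settings used TMM, and the run without scaling differed from the main fit in TMM alone, so the sign rested on the scaling. The gene stood in gonad at 0.0883% of its pituitary level. With a replicate block the counts were 3062 in brain, 3406 in pituitary, 951 in liver and 13407 in gonad. Female and male pools of the same number and tissue had a median correlation of -0.00435 (3 of 12 above 0.1), so the numbers did not pair; pools of one sex and number in 2 tissues had 0.0866 (14 of 36 above 0.1), against -0.0468 for other numbers. Between brain, pituitary and liver all 9 pairs of same-numbered female pools were above 0.1 (0.11 to 0.336), so female pools do pair across these tissues. Same-numbered male pools were positively correlated in each pair as well, less closely (0.0261 to 0.243). The fit among tissues, its splits and the overlaps between tissues leave these correlations out. Where no cause is given, it was not tested. Depth (10032337 to 25293744 counts) limits weakly expressed genes.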

Other observations

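Chosen after the result was seen were the tests here on RNA of another tissue, on wrongly assigned reads, on scaling and on one gene copy. Transcripts of other tissues were raised in single libraries. The oocyte list stood at 0.679% of its ovary level in male brain 1, 0.564% in male pituitary 3, 0.455% in female pituitary 3 and 0.176% in female liver 1, and the hepatocyte list stood at 2.85% of its female liver level in female gonad 2.

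Oocyte genes active in the male fish would leave W-linked genes unmoved, but the excess of W-linked genes in male brain 1 was 0.827 of that of the oocyte list. Reads assigned to the wrong library at one rate would have raised other lists in male brain 1 too, where the largest ratio of the hepatocyte, pancreas and pituitary lists was 0.999. In female pituitary 3 the hepatocyte and pancreas lists were raised with the oocyte list (3.27, 2.31 and 5.89 times), so wrongly assigned reads stayed open there. In male pituitary 3 the hepatocyte and pancreas lists stood at 1.57 and 1.55 times, and no test of this was set for male pituitary 3, female liver 1 and female gonad 2. RNA of another tissue stayed open as well: in each of the 5 libraries at least 80% of the abundant members of the list were at 2 times the others or more, but the libraries had been picked by these lists, so this decides nothing.

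Z-linked genes were lower in females. Reads taken up by W-linked copies of the same product name could not explain all of this in brain. Z-linked genes with no such copy still had a median log2 difference of -0.501, against -0.642 for those with one. Copies under another name or not placed on W were not found this way, so reads taken up by them stayed open. A scaling that shifts all genes would have moved autosomal genes as well, but Z-linked genes lay -0.562 from them in brain. One gene copy without full compensation may account for the share of at least 76.8% of Z-linked genes lower in females in brain, pituitary and liver; in gonad it was 67.1%. For genes with a copy on both chromosomes, the female sum of Z and W over the male Z level, on unscaled FPKM, had a median log2 of 0.0691 in brain, 0.129 in pituitary and 0.0579 in liver, where the W copy may make up the difference. In gonad this was left open, since without scaling the median gene already stood at -1.04.

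The 6 libraries of a tissue can be split in 10 ways, too few for a share under 0.05. In brain, pituitary, liver and gonad 1 of 10 splits gave as many called genes as the real one; the highest other counts were 1, 0, 0 and 0 against 3318, 4086, 721 and 13632. For the gene lists, adjusted within each tissue here, 10, 10, 9 and 9 of 10 splits gave as many calls as the real one, with real counts of 1, 0, 2 and 10 and highest other counts of 6, 7, 6 and 13. The pituitary count says nothing, since with a real count of 0 every split gives as many. In brain and liver other splits called several times more lists, which points to a structure of the samples or to a preset correlation set too low; these were not told apart by a test.

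In liver, 9 hormone genes stood at 0.0514 to 0.0767% of their pituitary level, and gh1 lay at 30.2 to 31.1 FPKM in all 6 livers.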
